A study of Homo sapiens with 12 samples.

How the data were processed

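RNA sequencing was done on 12 libraries of MDA-MB-468 cells, 3 for each combination of vector (THRB or empty) and treatment (10 nM T3 or vehicle, 24 hours). Per the labels' protocols, libraries were made with the NEBNext Ultra II RNA kit; how ribosomal RNA was removed is not given in the sources used here. Per the submitters' processing notes, the tools were CASAVA 1.7, STAR 2.7, HTSeq 0.10 and DESeq2, with build hg38; whether counting used strand is not given in the sources used here, so overlapping and antisense genes are uncertain. The authors deposited whole-number counts per gene for each library. They also deposited a table of normalized values, treated here as a score, which equalled the counts divided by 1 factor per library and rounded, to within 1 for every gene; it served only to check the columns.

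Lines that name no gene were left out of library sizes and tests; they held 31.87% to 39.24% of the alignments. Gene totals ranged from 4241863 to 11955825 counts. Intervals and floors (3 counts over a group) cover counting error only, since reads without molecular identifiers are not independent molecules; intervals are exact binomial at 95%. Gene names were matched to a GENCODE annotation of hg38 for coordinates, gene type and GC content: 29502 of 56832 names matched by symbol and 887 through an older symbol, 53% in all, and 88.7% of the genes tested had a GC value.

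Tests used edgeR 4.0.16 with limma 3.58.1 in R 4.3.3: filterByExpr (at least 10 counts, 15 in total), TMM, robust dispersions and the quasi-likelihood test on 1 fit of 4 group means with 8 residual degrees of freedom, Benjamini-Hochberg adjusted p below 0.05 over 14549 genes. CPM are scaled by TMM factors, and SE is the log2 fold change over the root of F. Of 45 gene lists fixed before the data were examined, 41 had 5 or more measured members and were tested by camera with a preset correlation of 0.01, and again with an estimated one and with fry. With an estimated correlation camera draws on the 8 residual degrees of freedom, and with a preset one on the number of genes. Camera compares a list with all other genes, whereas fry asks only whether the members of a list changed. Fibroblast, leukocyte, thyroid follicular and neural crest marker lists had too few members; of 5 endothelial markers T3 raised 2 and lowered 1 in TRB cells. Steps were tested on simulated counts in which 200 genes changed, fewer than any real comparison called. These were drawn from genes with a mean above 1 CPM, 50 for each fold change, so recovery of lower genes was not tested. False calls there set no error rate for the real results. For T3 in TRB cells on 14339 genes, 98% of 4-fold, 86% of 2-fold, 80% of 1.5-fold and 44% of 1.2-fold changes were recovered with 11 false calls. Recovery of 1.5-fold and 1.2-fold changes was 82% and 32% for T3 in EV cells, 72% and 24% for TRB without T3, 82% and 62% for TRB with T3, and 56% and 24% for the interaction, with 11, 13, 10 and 7 false calls; 2-fold changes were recovered in 86%, 82%, 78% and 86% and 4-fold changes in 96%, 98%, 100% and 94%. With a GC trend put into simulated counts for T3 in TRB cells, the fit with GC offsets made 10 false calls on 12912 genes and the fit without them 7695 on 12796 genes.

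The named genes were THRB; the 8 highest and 8 lowest log2 fold changes per comparison among called genes with a mean of 1 CPM or more in the higher group and no overlap between groups (which 10% of unrelated groups of 3 show), leaving out unnamed loci; the 3 members with the smallest p of each list called by camera; THRA, KLF9, HR, DIO1, THRSP, JAK1 and RUNX2 whatever their values; and the 8 smallest p for the interaction. Some genes that this rule takes are not reported here. Alternatives fixed beforehand were DESeq2 1.42.0, RLE normalization, no filter, CPM above 1 in 3 libraries, a fit of the compared groups alone, the replicate number as a block, each library left out in turn, and the estimated correlation. Added after seeing the data were counts thinned to 4241863 per library, protein-coding genes only (12388), offsets for the GC trend, and the estimated correlation with each library left out in turn.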

Results

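MDA-MB-468 is a basal-like human breast cancer cell line. Cells that stably carried a vector for thyroid hormone receptor beta (the TRB pool) or the empty vector (the EV pool) were starved of hormone and then given the thyroid hormone T3 at 10 nM or vehicle for 24 hours. RNA sequencing counts were available for 3 libraries in each of the 4 combinations of vector and treatment, 12 in all. Counts assigned to genes came to 7578831, 8904361 and 7311623 in the TRB vehicle libraries and 11915181, 11335783 and 11501295 in the TRB T3 libraries. The EV vehicle libraries held 4241863, 6336559 and 7851876 and the EV T3 libraries 10323437, 11381879 and 11955825, so every T3 library was deeper than every vehicle library. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each vector is represented by 1 stable pool in the labels, and every difference between TRB and EV libraries is a difference between those pools.

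The receptor gene itself was measured first. THRB (chromosome 3, 24117153 to 24495756) stood at 43.4 ± 0.824 CPM in EV vehicle libraries and 140 ± 4.15 CPM in TRB vehicle libraries (SD, n = 3). Under T3 it stood at 38.5 ± 1.23 CPM in EV libraries and 329 ± 16.7 CPM in TRB libraries. Reads from the vector and from the cell's own gene cannot be separated in these counts. The first principal component of log2 CPM held 49.2% of the variance and placed the TRB T3 libraries apart from the other 9. Component 3 (6.9%) set EV vehicle replicate 1 apart, at -30.65, and component 4 (4.7%) EV vehicle replicate 2, at -24.34.

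**Figure D1:**
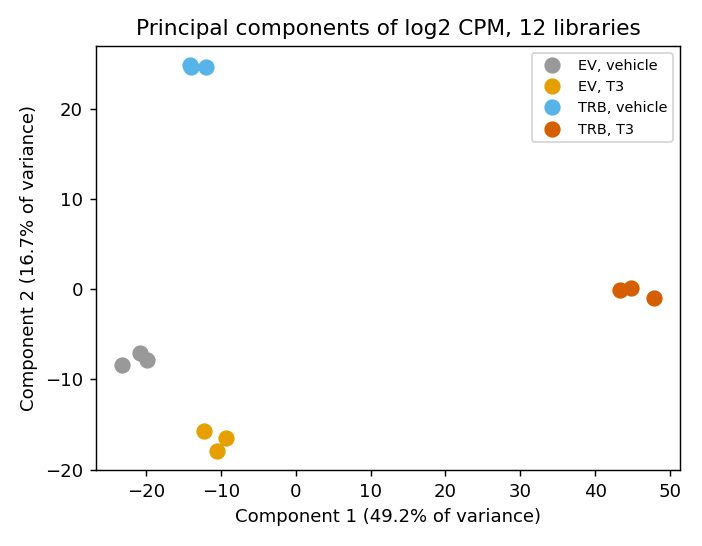
Principal components of log2 CPM for the 12 libraries, with component 1 (49.2% of the variance) on the horizontal axis and component 2 (16.7%) on the vertical axis; each point is 1 library, coloured by group. The 3 TRB T3 libraries lie at 43.25 to 47.79 on component 1, and every other library lies below 0.

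The first comparison asked what T3 changed in cells with the added receptor. The T3 targets KLF9 and HR rose, as did most interferon gamma response and antigen presentation genes, and most basal epithelial markers and cholesterol synthesis genes fell. KLF9 (chromosome 9, 70384597 to 70414624), a transcription factor induced by T3, went from 2.44 ± 0.502 to 27.1 ± 0.382 CPM (SD, n = 3). HR (chromosome 8, 22114415 to 22133384), a corepressor gene that T3 induces, went from 61.6 ± 2.69 to 220 ± 10.2 CPM, and TNFSF10 (chromosome 3, 172505508 to 172523507), which encodes the death ligand TRAIL, from 51.8 ± 1.45 to 329 ± 2.94 CPM. KRT5 (chromosome 12, 52514575 to 52520687), a basal keratin, went from 900 ± 55.8 to 224 ± 23.5 CPM. Of 14549 genes tested, 3264 rose and 3192 fell by edgeR's quasi-likelihood test (Benjamini-Hochberg adjusted p below 0.05), 585 and 346 of them by 2-fold or more. Thinned to equal depth, 71% of these calls were left with their direction. The T3 libraries were also lower in mitochondrial ribosomal RNA, so any part due to library handling cannot be told apart from T3.

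The largest increases in TRB cells were led by APLN, the gene of the peptide hormone apelin, at 0.336 ± 0.0735 CPM with vehicle and 48 ± 3.59 CPM with T3 (SD, n = 3). C15orf59 rose by 6.52 and IL6R, the interleukin 6 receptor, by 5.41 on the log2 scale. IGFBP7 and TSPAN18 had no count in the vehicle libraries and were at least 11.6-fold and 10.7-fold higher with T3, against a floor of 3 counts over the group. KCNJ12 and LDLRAD1 had 1 count in the vehicle group, with ratios of 86.3 (95% counting interval 15.2 to 3430) and 58.9 (10.3 to 2350). PPARGC1A, a coactivator of mitochondrial gene expression, had 3 vehicle counts and a ratio of 45.2 (15.2 to 221). Among the largest decreases, SNCAIP and FZD8 had 3 and 2 counts with T3 and were 34.1-fold (11.2 to 169) and 27-fold (6.97 to 231) lower. SLITRK6 (-4.09), VNN2 (-3.72), EDN2 (-3.62) and CD180 (-3.59) fell on the log2 scale. The mitochondrial ribosomal RNAs MT-RNR1 and MT-RNR2 also fell, with log2 fold changes of -4.6 and -3.75; they were lower in the T3 libraries of both pools.

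Lists of genes fixed before the data were examined were compared with all other genes by camera with a preset correlation of 0.01. Each test was repeated with a correlation estimated from the data. Over all comparisons 21 calls passed with the estimated correlation, and 15 of these did so whichever library was left out; the exceptions are given with their lists. In TRB cells T3 changed 17 of 41 lists with the preset correlation and 6 with an estimated one. Those 6 were thyroid hormone responsive genes, interferon gamma response, apoptosis effectors, basal markers, RUNX2 targets and cholesterol synthesis.

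Of 23 thyroid hormone responsive genes 14 rose and 5 fell (adjusted p = 0.00107 with an estimated correlation), with FURIN at a log2 fold change of 2.48, UCP2 at 1.56 and HR at 1.83. Of 25 interferon gamma response and antigen presentation genes 22 rose and 0 fell (adjusted p = 0.0183 with an estimated correlation), among them the transcription factor IRF1 (1.99) and the guanylate binding proteins GBP2 (1.07) and GBP3 (1.34). Apoptosis effectors split, 12 of 31 higher and 7 lower (adjusted p = 0.0324 with an estimated correlation, but 0.0518 and 0.0528 without TRB vehicle replicates 2 and 3); TNFSF10 (2.67), the BH3-only gene BMF (3.13) and the TRAIL receptor TNFRSF10A (1.42) rose. Basal and myoepithelial markers fell in 19 of 27 cases and rose in 4 (adjusted p = 0.0223 with an estimated correlation), with KRT17 at -1.61, KRT5 at -2.01 and SOX9 at -0.88. Of 25 cholesterol synthesis genes 16 fell and 4 rose (adjusted p = 0.0223 with an estimated correlation), including HMGCS1 (-0.91), INSIG1 (-1) and FDFT1 (-0.66). The 7 measured genes of the RUNX2 list had 4 higher and 1 lower (adjusted p = 0.0223 with an estimated correlation, and 0.222 with the preset correlation and no filter on low counts); CCND1 rose by 1.3 and VEGFA by 1.86, and the collagen chaperone gene SERPINH1 fell by 0.5. The counts adjusted over the list alone were 14 and 5, 22 and 0, 13 and 8, 19 and 4, 16 and 4, and 4 and 3 for these lists in the same order.

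By camera the other lists passed only with the preset correlation. All of them passed by fry (fry adjusted p up to 0.0159), which does not compare a list with other genes. Mitosis (G2/M) genes fell in 50 of 59 cases and rose in 1 (adjusted p = 0.087 with an estimated correlation), with CDC25B at -0.68, ANLN at -0.58 and CDC20 at -0.45. S phase genes fell in 35 of 57 cases and rose in 3 (adjusted p = 0.279 with an estimated correlation): TYMS stood at -0.56 and MCM4 at -0.36, whereas RFC3 rose by 0.96. All 19 replication dependent histone genes fell (adjusted p = 0.219 with an estimated correlation), with HIST1H1B at -0.6, HIST1H3B at -0.44 and HIST2H2BE at -0.58. Of 71 ribosomal protein genes 40 fell and 2 rose (adjusted p = 0.771 with an estimated correlation), with RPS4X at -0.28 and RPS27 at -0.27. Junction genes fell in 16 of 26 cases and rose in 5 (adjusted p = 0.347 with an estimated correlation), with DSC2 at -0.88, CLDN1 at -1.6 and CLDN7 at 0.59. YAP-TAZ targets fell in 13 of 22 and rose in 3 (adjusted p = 0.261 with an estimated correlation), with IGFBP3 at -1.98, AJUBA at -0.87 and WWTR1, which encodes TAZ, at 0.58.

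NF-kB targets rose in 10 of 21 cases and fell in 2 (adjusted p = 0.0692 with an estimated correlation), led by TNFAIP2 (1.42), BCL3 (1.31) and CSF1 (1.76). EGFR and ERK feedback genes rose in 15 of 26 and fell in 4 (adjusted p = 0.0692 with an estimated correlation), with CCND1, DUSP4 (0.87) and IER3 (0.64). Type I interferon genes rose in 20 of 43 and fell in 4 (adjusted p = 0.771 with an estimated correlation), with PARP14 at 0.78, TRIM22 at 0.84 and LGALS3BP at 0.44. Estrogen responsive genes split, 11 of 20 higher and 8 lower (adjusted p = 0.191 with an estimated correlation), with RET at 3.82 and RARA at 0.94, and without TRB T3 replicate 1 that list missed the threshold (camera adjusted p = 0.0549). Glycolysis genes rose in 12 of 23 and fell in 4 (adjusted p = 0.5 with an estimated correlation), with PFKFB3 at 2.03, HK2 at 0.66 and LDHA at -0.59; that list missed the threshold without TRB vehicle replicate 2 (camera adjusted p = 0.0635) or TRB T3 replicate 2 (0.0792), and also thinned to equal depth (0.0859), on protein-coding genes (0.0783), with the GC trend removed (0.0726) and in a fit of the compared groups alone (0.0676). With no filter on low counts the estrogen list missed it too (0.0924). Of the genes named whatever their values, THRA, the other T3 receptor gene, fell by 1.39, THRSP rose by 3.72 and RUNX2 by 1.01, and JAK1 fell by 0.16. DIO1 had 11 counts over all libraries and was not tested.

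**Figure D2:**
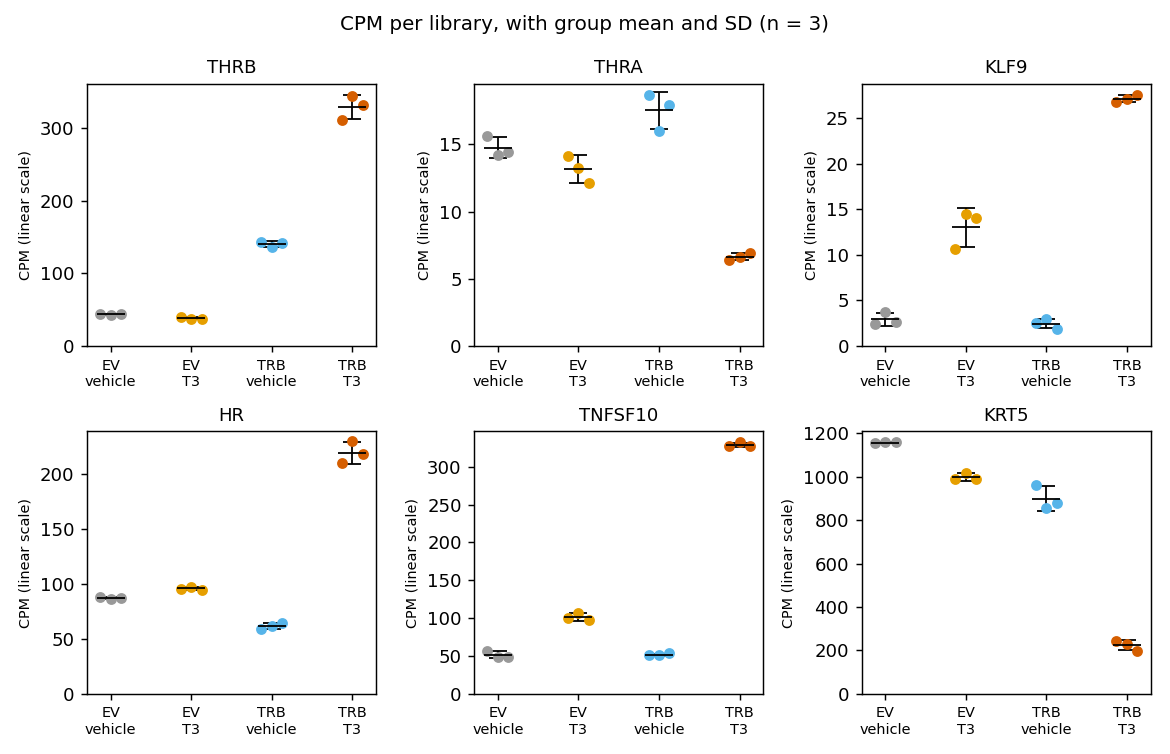
CPM (linear axis from 0) of THRB, THRA, KLF9, HR, TNFSF10 and KRT5 in the 4 groups; points are libraries, horizontal bars are group means and error bars are SD (n = 3). KLF9 averaged 13 CPM in EV cells with T3 and 27.1 CPM in TRB cells with T3, and KRT5 was lowest, at 224 CPM, in TRB cells with T3.

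The second comparison asked what T3 changed in cells with the empty vector. KLF9 rose from 2.95 ± 0.714 to 13 ± 2.1 CPM and TNFSF10 from 51.7 ± 4.63 to 101 ± 4.98 CPM (SD, n = 3). In all, 413 genes rose and 247 fell, 26 and 10 of them by 2-fold or more, and DESeq2 called 372 genes (250 and 122) in place of 660. The count was 275 (180 and 95) without EV vehicle replicate 3, 396 (280 and 116) without EV vehicle replicate 1, 341 (242 and 99) without EV T3 replicate 2 and 408 (283 and 125) with counts thinned to equal depth. With no filter on low counts 403 rose and 136 fell, and with the GC trend removed 353 of 656 called genes rose and the others fell. The increases were led by C1QTNF1 (log2 fold change 2.7), KLF9 (2.13), C15orf59 (1.77), the metallothionein MT1X (1.74) and the sulfotransferase SULT1A2 (1.67). MT-TE (2.6), C7orf55 (1.56) and FAM131B (1.5) also passed, but each missed the threshold when some single library was left out: MT-TE without EV vehicle replicate 2 (edgeR adjusted p = 0.0745) or EV T3 replicate 1 (0.0742), C7orf55 without EV vehicle replicates 2 or 3 or EV T3 replicate 2 (up to 0.135), and FAM131B without any EV vehicle replicate or EV T3 replicate 3 (up to 0.21).

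Of the 8 largest decreases in EV cells, 6 were structured RNAs, whose recovery depends on how a library is made. MT-RNR1 stood at -5.66, MT-RNR2 at -4.29, SNORA22 at -1.9, SNORA74B at -1.81, RNVU1-7 at -1.18 and RNY1 at -1.17. MT-RNR1 missed the threshold without EV T3 replicate 2 (edgeR adjusted p = 0.0583), MT-RNR2 without EV vehicle replicate 3 or any EV T3 replicate (up to 0.0892), and SNORA74B and RNVU1-7 without EV vehicle replicate 3 (0.0768 and 0.064). The others were the keratin KRT75 (-1.06), which missed it without any 1 of 5 libraries (up to 0.172), all but EV T3 replicate 1, and ART3 (-1.02). In a fit of the EV libraries alone MT-RNR1 and MT-RNR2 missed the threshold (edgeR adjusted p = 0.0976 and 0.118). With counts thinned to equal depth RNVU1-7, RNY1 and ART3 did (0.26, 0.124 and 0.0527), as did FAM131B (0.0725), which also missed it with no filter on low counts (0.0568). THRB (-0.18, edgeR adjusted p = 0.147), THRA (-0.16, 0.555), HR (0.14, 0.135), THRSP (1.24, 0.385), JAK1 (-0.12, 0.0714) and RUNX2 (0.25, 0.24) did not pass; JAK1 did without EV T3 replicate 2 (0.0397).

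In EV cells 8 lists passed with the preset correlation and 3 with an estimated one. By fry all 8 passed but type I interferon genes (fry adjusted p = 0.221). Interferon gamma response genes rose in 11 of 25 cases and none fell (adjusted p = 0.0435 with an estimated correlation, but 0.0578 to 0.115 without any 1 of 5 libraries, all but EV vehicle replicate 2), with IRF1 at 0.5, HLA-B at 0.27 and PSMB8 at 0.33. Thyroid hormone responsive genes rose in 4 of 23 and fell in 1 (adjusted p = 0.0272 with an estimated correlation, but 0.0515 without EV vehicle replicate 3 and 0.0588 without EV T3 replicate 2), with UCP2 at 0.36 and the clock gene DBP at 0.69. Apoptosis effectors rose in 3 of 31 (adjusted p = 0.0435 with an estimated correlation, but 0.134 and 0.0849 without EV vehicle replicates 1 and 3 and 0.0846 and 0.135 without EV T3 replicates 2 and 3): TNFSF10 by 0.99, BMF by 0.55 and TNFRSF10A by 0.44, the last of which missed the threshold by DESeq2 (adjusted p = 0.0602) and without EV vehicle replicates 1 or 3 or EV T3 replicate 2 (up to 0.17), and BMF without EV vehicle replicate 3 (0.0771). Mitosis genes fell in 6 of 59 (adjusted p = 0.203 with an estimated correlation), with MKI67 at -0.19, NUSAP1 at -0.19 and ANLN at -0.14. Basal markers fell in 8 of 27 (adjusted p = 0.151 with an estimated correlation), with ITGB4 at -0.26, SOX9 at -0.21 and KRT6A at -0.68. Type I interferon genes rose in 6 of 43 (adjusted p = 0.617 with an estimated correlation), with IFIT3 at 0.44, XAF1 at 0.61 and LGALS3BP at 0.18; XAF1 missed the threshold without EV vehicle replicate 3 (edgeR adjusted p = 0.064). Immediate early genes rose in 3 of 27 (adjusted p = 0.151 with an estimated correlation), IER5 by 0.34, IER3 by 0.27 and IER2 by 0.29; that list missed the threshold without EV vehicle replicate 3 (camera adjusted p = 0.0609) and with the GC trend removed (0.231). Receptor coregulators fell in 3 of 23 (adjusted p = 0.151 with an estimated correlation), with CREBBP at -0.22, NCOA1 at -0.17 and MED1 at -0.18; by DESeq2 NCOA1 and MED1 missed the threshold (adjusted p = 0.113 and 0.15). NUSAP1, ANLN, CREBBP, NCOA1 and MED1 each missed the threshold without EV vehicle replicate 3 (edgeR adjusted p = 0.0541, 0.166, 0.237, 0.227 and 0.356) and without EV T3 replicate 2 (0.0713, 0.0948, 0.0994, 0.116 and 0.151). Without EV vehicle replicate 1 this held for NUSAP1, ANLN, NCOA1 and MED1 (0.0722, 0.0636, 0.215 and 0.0774), and without EV T3 replicate 1 for ANLN, NCOA1 and MED1 (0.0693, 0.0759 and 0.0966). Thinned to equal depth, NCOA1, MED1 and TNFRSF10A missed it (0.517, 0.0547 and 0.111); with the GC trend removed NCOA1, MED1 and LGALS3BP did (0.0504, 0.0521 and 0.0639), with no filter on low counts NCOA1, MED1 and ANLN (0.0992, 0.164 and 0.177), and in a fit of the EV libraries alone MED1 (0.0527).

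The T3 effects in the 2 pools rest on separate libraries and could be set against each other. T3 libraries of both pools were deeper and lower in MT-RNR1 and MT-RNR2, so handling shared by them would raise the overlap too. Fisher's exact test also treats genes as independent, so its p-values overstate the evidence where genes vary together. Of the genes that rose, 336 did so in both pools, against 92.7 for independent lists (Fisher's exact test, two-sided, p = 1.29e-147), and of those that fell 199 did, against 54.2 (p = 3.4e-87). Both directions together held 535 genes, but 245 without EV vehicle replicate 3, 346 without EV vehicle replicate 1, 307 without EV T3 replicate 2, 317 by DESeq2 and 319 with counts thinned to equal depth. Of the 660 genes called in EV cells 92.3% had the same sign in TRB cells, with a median ratio of TRB to EV log2 fold change of 1.86. The test of the difference itself called 3470 genes, 1783 with a more positive T3 effect in TRB cells and 1687 with a more negative one. DESeq2 called 2399 genes, 1282 more positive and 1117 more negative. The smallest p-values belonged to C2orf54 (difference of log2 fold changes 2.52), the monoacylglycerol lipase MGLL (2.62), SERPINB1 (1.97), SYT12 (1.77), TNS1 (2.34), TP53INP2 (1.89), CPNE2 (2.27) and IGFBP3 (-1.64). MGLL went from 61.1 ± 3.19 to 80.8 ± 1.82 CPM in EV cells and from 41.1 ± 2.9 to 334 ± 4.64 CPM in TRB cells (SD, n = 3).

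By lists, 15 differed between pools with the preset correlation and 5 with an estimated one. Those 5 were thyroid hormone responsive genes (11 of 23 more positive in TRB cells and 3 more negative, adjusted p = 0.00505 with an estimated correlation), interferon gamma response (20 of 25 more positive and 0 more negative, 0.0212), basal markers (17 of 27 more negative and 3 more positive, 0.0205), RUNX2 targets (3 of 7 more positive and 1 more negative, 0.0205) and cholesterol synthesis (15 of 25 more negative and 1 more positive, 0.0205). The other lists were apoptosis effectors, S phase, mitosis, junction, EGFR and ERK feedback, NF-kB, YAP-TAZ, hypoxia, ribosomal protein and histone genes, with adjusted p between 0.0565 and 0.666 with an estimated correlation. By fry all of these passed but ribosomal protein genes (fry adjusted p = 0.0525). With no filter on low counts the RUNX2 and hypoxia lists missed the threshold (camera adjusted p = 0.105 and 0.0518).

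**Figure D3:**
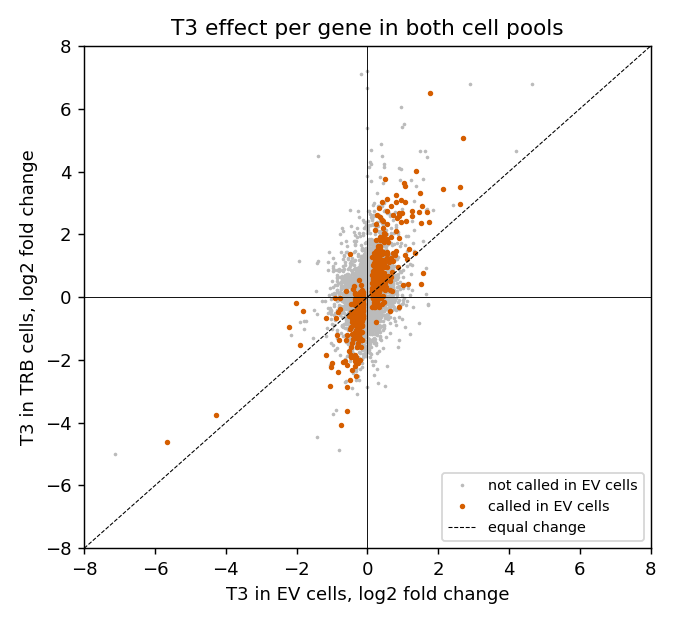
Log2 fold change with T3 in EV cells (horizontal axis) and TRB cells (vertical axis) for the 14549 genes tested; each point is 1 gene, coloured points are the 660 genes called in EV cells, and the dashed line marks equal change. Most coloured points lie farther from 0 on the vertical axis, with a median ratio of 1.86.

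The third comparison asked how the TRB pool differed from the EV pool without T3. Many interferon stimulated genes, NF-kB targets, basal markers and ERK feedback genes were lower in TRB cells. IFIT3, an interferon stimulated gene on chromosome 10 (89327894 to 89340971), stood at 13.2 ± 1.25 CPM in TRB and 28.7 ± 1.89 CPM in EV cells, and IRF1 (chromosome 5, 132481609 to 132490798) at 33.6 ± 1.39 and 55.8 ± 3.02 CPM (SD, n = 3). THRB was higher by 1.69 ± 0.06 (SE) on the log2 scale. In all, 1143 genes were higher and 1077 lower, and DESeq2 called 1417 genes (670 and 747) in place of 2220; without EV vehicle replicate 3, 758 were higher and 804 lower. TMPRSS11BNL had no count in EV vehicle libraries and was at least 9.04-fold higher. PLCB1 (ratio 34.1, 95% counting interval 5.81 to 1380), ZC4H2 (11.1, 3.55 to 55.9), PDGFD and DOCK2 (each 10.1, 2.52 to 87.5) had 1 to 3 counts in EV vehicle libraries. STON2 (3.76), VGLL3 (3.45) and LBP (3.19) were higher on the log2 scale. The desmosomal cadherin DSG1 had 1 count in TRB cells and was 50.4-fold lower (8.52 to 2040). GCNT1 (-3.31), the stress cytokine gene GDF15 (-3.18), IFI44L (-2.55), ALPPL2 (-2.37), IFI6 (-2.2), ALPP (-2.19) and UPB1 (-1.97) were also lower.

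In this comparison 14 lists passed with the preset correlation and 5 with an estimated one. Type I interferon genes were lower in 32 of 43 cases and higher in 0 (adjusted p = 0.0294 with an estimated correlation, but 0.0545, 0.0531 and 0.0583 without TRB vehicle replicates 1, 2 and 3 and 0.0543 without EV vehicle replicate 1), with PARP14 at -0.54, IFIT3 at -1.12 and OAS3 at -0.54. Interferon gamma response genes were lower in 17 of 25 and higher in 1 (adjusted p = 0.0223 with an estimated correlation), including the peptide transporter genes TAP1 (-0.7) and TAP2 (-0.75) and IRF1 (-0.74). NF-kB targets were lower in 11 of 21 and higher in 1 (adjusted p = 0.00746 with an estimated correlation), with complement C3 at -1.32, TNFAIP2 at -0.58 and BIRC3 at -0.7. EGFR and ERK feedback genes were lower in 13 of 26 and higher in 2 (adjusted p = 0.00737 with an estimated correlation), with CCND1 at -0.56, IER3 at -0.38 and PHLDA1 at -0.46. Basal markers were lower in 13 of 27 and higher in 2 (adjusted p = 0.0294 with an estimated correlation, but 0.0531 without TRB vehicle replicate 2 and 0.0543 without EV vehicle replicate 1), with KRT14 at -1.28, KRT16 at -1.01 and KRT17 at -0.56.

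By camera the remaining 9 lists passed only with the preset correlation. All 9 passed by fry (fry adjusted p up to 0.0272), which does not compare a list with other genes. Luminal markers were higher in 7 of 23 and lower in 2 (adjusted p = 0.315 with an estimated correlation), with XBP1 at 0.49, FOXA1 at 0.38 and SPDEF at 0.25. Histone genes were higher in 10 of 19 (adjusted p = 0.315 with an estimated correlation), with HIST1H3B and HIST1H1B at 0.23 and HIST2H2AC at 0.29. Cholesterol synthesis genes were higher in 9 of 25 and lower in 1 (adjusted p = 0.177 with an estimated correlation), with SC5D at 0.34 and INSIG1 at 0.29. Immediate early genes were lower in 10 of 27 and higher in 3 (adjusted p = 0.0831 with an estimated correlation), with MYC at -0.39 and CTGF at -0.85. YAP-TAZ targets were lower in 6 of 22 and higher in 1 (adjusted p = 0.258 with an estimated correlation), with IGFBP3 at -0.7 and TGFB2 at -0.24. Heat shock genes were lower in 9 of 18 (adjusted p = 0.329 with an estimated correlation), with HSP90AB1 at -0.23, HSPD1 at -0.21 and FKBP4 at -0.23. Unfolded protein response genes were lower in 9 of 33 and higher in 1 (adjusted p = 0.315 with an estimated correlation), with PSAT1 at -0.29 and HSPA5 at -0.17, whereas XBP1 was higher; without EV vehicle replicate 2 that list missed the threshold (camera adjusted p = 0.0646). The hormone transport list, which holds THRB itself, had 2 of 9 higher and 2 lower (adjusted p = 0.0831 with an estimated correlation), with SLC7A5 at -0.59. For the RUNX2 list the test pointed down with 2 of 7 lower and 1 higher, while its median was 0.005 and its mean -0.019 (adjusted p = 0.177 with an estimated correlation); VEGFA stood at -0.33, and SERPINH1 at 0.15 missed the threshold by DESeq2 (adjusted p = 0.173) and in 5 of the 6 fits that left out 1 library, all but EV vehicle replicate 1 (up to 0.346); it also missed it with RLE normalization (edgeR adjusted p = 0.0593), the replicate number as a block (0.0584), no filter (0.132), thinned counts (0.592) or protein-coding genes (0.0526). That list missed the threshold without TRB vehicle replicates 1 or 2 (camera adjusted p = 0.071 and 0.0647), with the GC trend removed (0.086) and with no filter on low counts (0.375), where the hormone transport list did as well (0.105). HR was lower (-0.5). THRA (0.25, edgeR adjusted p = 0.147), KLF9 (-0.27, 0.581), THRSP (1.81, 0.0515), JAK1 (0.11, 0.0588) and RUNX2 (-0.23, 0.247) did not pass; THRSP did with the GC trend removed (0.0464) or on protein-coding genes (0.0485), and JAK1 with the GC trend removed (0.0318) or in a fit of the compared groups alone (0.0268).

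**Figure D4:**
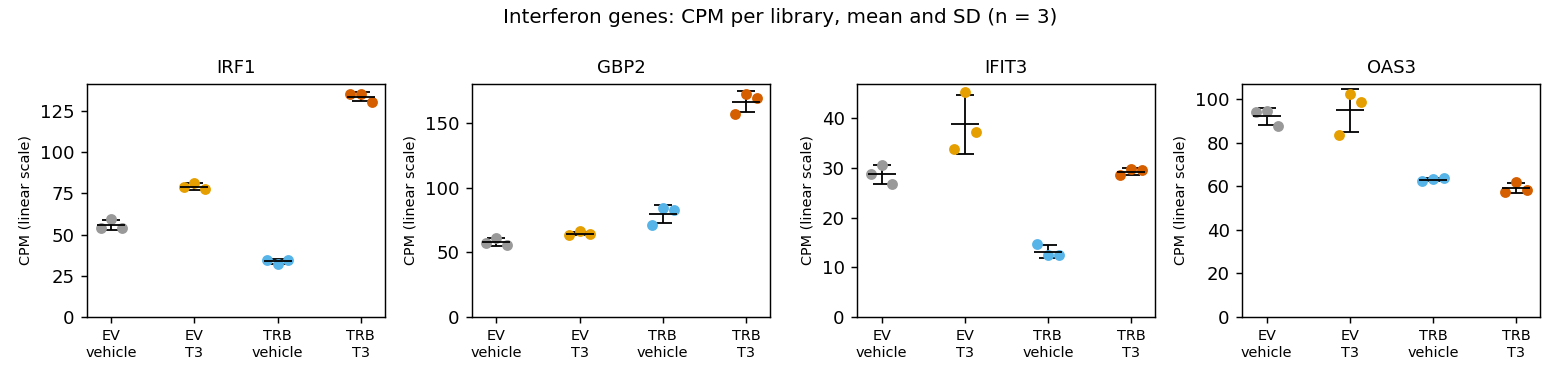
CPM (linear axis from 0) of IRF1, GBP2, IFIT3 and OAS3 in the 4 groups; points are libraries, horizontal bars group means and error bars SD (n = 3). IRF1 averaged 33.6 CPM in TRB cells without T3 and 134 CPM with T3, against 55.8 and 79.2 CPM in EV cells.

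The fourth comparison set the TRB pool against the EV pool with T3 in both. Most basal markers were lower in TRB cells, and the T3 targets KLF9 and HR were higher. THRB was higher by 3.1 ± 0.05 (SE) on the log2 scale. In all, 3056 genes were higher and 2860 lower. PPARGC1A had no count in EV T3 libraries and was at least 63.9-fold higher, as were TMPRSS11BNL (at least 24.5-fold), SPATA3 (at least 15.5-fold) and TSPAN18 (at least 15.2-fold). RFTN1 had 1 count in EV cells and a ratio of 156 (95% counting interval 27.6 to 6200). APLN (7.59), OLFML2B (5.36) and BSND (5.16) were higher on the log2 scale. DSG1 had no count in TRB cells and was at least 28.6-fold lower. SERPINB3 and SNCAIP had 3 counts there and were 15.8-fold (5.09 to 79.6) and 13.4-fold (4.27 to 67.9) lower. ZNF365 (-3.73), KRT75 (-3.28), CD180 (-3.23), RGS2 (-3.06) and IFI27 (-2.98) were lower as well.

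With T3 in both pools 16 lists passed with the preset correlation and 2 with an estimated one. Basal markers were lower in 22 of 27 and higher in 4 (adjusted p = 0.00509 with an estimated correlation), with KRT14 at -2.61, KRT16 at -2.75 and KRT17 at -2.09. Thyroid hormone responsive genes were higher in 13 of 23 and lower in 5 (adjusted p = 0.00509 with an estimated correlation), with FURIN at 2.29, HR at 1.19 and UCP2 at 1. By camera the other lists passed only with the preset correlation, and all of them passed by fry (fry adjusted p up to 0.00481). Of these, type I interferon genes were lower in 30 of 43 and higher in 2 (adjusted p = 0.402 with an estimated correlation), with OAS1 at -1.15, OAS3 at -0.69 and IFITM1 at -1.33. Interferon gamma response genes were higher in 13 of 25 and lower in 3 (adjusted p = 0.354 with an estimated correlation), with GBP2 at 1.37, IRF1 at 0.76 and GBP4 at 3.12. Apoptosis effectors were higher in 13 of 31 and lower in 6 (adjusted p = 0.0959 with an estimated correlation), with BMF at 2.81, TNFSF10 at 1.7 and BCL2L11 at 0.79. Mitosis genes were lower in 40 of 59 and higher in 1 (adjusted p = 0.175 with an estimated correlation), with CDC25B at -0.57, MYBL2 at -0.46 and CDC20 at -0.42, and S phase genes in 30 of 57, with 3 higher (adjusted p = 0.354 with an estimated correlation), with TYMS at -0.58 and ATAD2 at -0.4 but GINS3 at 0.84. Histone genes were lower in 18 of 19 (adjusted p = 0.402 with an estimated correlation), with HIST1H3B and HIST1H1C at -0.34 and HIST1H1D at -0.36. Ribosomal protein genes were lower in 43 of 71 and higher in 1 (adjusted p = 0.623 with an estimated correlation), with RPL8 at -0.4 and RPS2 at -0.35.

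YAP-TAZ targets were lower in 15 of 22 and higher in 3 (adjusted p = 0.0959 with an estimated correlation), with IGFBP3 at -2.34, TGFB2 at -0.59 and AJUBA at -0.97. TGF-beta targets were lower in 12 of 26 and higher in 6 (adjusted p = 0.101 with an estimated correlation), with INHBA at -2.72 and TGFB1 at -1.31 but ID2 at 1.14. Cholesterol synthesis genes were lower in 15 of 25 and higher in 4 (adjusted p = 0.0959 with an estimated correlation), with HMGCS1 at -0.68, ACAT2 at -0.65 and SQLE at -0.81. Heat shock genes were lower in 9 of 18 and higher in 2 (adjusted p = 0.402 with an estimated correlation), with HSPB1 at -1.59, HSPA1B at -0.57 and HSPA1A at -0.56; the last pair are near-identical copies whose counts are uncertain. Junction genes were lower in 15 of 26 and higher in 3 (adjusted p = 0.354 with an estimated correlation), with CLDN1 at -2.19 and DSC2 at -0.62 but CDH1 at 0.46. The RUNX2 list had 4 of 7 higher and 2 lower (adjusted p = 0.0959 with an estimated correlation), with VEGFA at 1.43, CCND1 at 0.53 and SERPINH1 at -0.43. For the hormone transport list the test pointed up while the median was -0.254 and the mean -0.011, with 4 of 9 higher and 4 lower (adjusted p = 0.0959 with an estimated correlation). That list holds THRB, which the vector itself raises, and it was not tested without THRB, so its upward direction says nothing of the other members. SULT1A1 stood at 1.35 and SLC7A5 at -0.83. With no filter on low counts the hormone transport, RUNX2 and apoptosis effector lists missed the threshold (camera adjusted p = 0.97, 0.201 and 0.079). THRA was lower (-0.98), and KLF9 (1.05), THRSP (4.29) and RUNX2 (0.52) were higher. JAK1 (0.08, edgeR adjusted p = 0.112) did not pass, but did without EV T3 replicate 2 (0.038).

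The pool differences without and with T3 also rest on separate libraries. Of the genes higher in TRB cells 546 were higher in both, against 240.1 for independent lists (Fisher's exact test, two-sided, p = 4.1e-99), and of the lower ones 491, against 211.7 (p = 2.04e-90). Both directions together held 1037 genes, but 645 by DESeq2 and 638 with counts thinned to equal depth. The agreement was partial. Of the 2220 genes called without T3, 67.3% had the same sign with T3. Their median ratio of the log2 fold change with T3 to that without T3 was 0.43. Another 211 and 181 genes were called in both with opposite signs. No count for independent lists was worked out for these, so they show no excess.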

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

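Tests of depth, GC content, ribosomal RNA, single libraries and pools, and the tests of handling on protein-coding and structured RNA calls, were chosen after the results were seen; the regroupings of libraries and the first test of handling were not. The T3 effect differed between TRB and EV cells for 3470 genes and 15 lists by the interaction test. For T3 in the 2 pools 19 genes were called with opposite signs, beside 535 with the same sign. For TRB without and with T3 these numbers were 392 and 1037. No count of opposite calls for independent lists was worked out, so neither 19 nor 392 shows an excess. The differences of T3 effects (TRB minus EV, log2) were 2.52 for C2orf54, 2.62 for MGLL, 1.97 for SERPINB1, 1.77 for SYT12, 2.34 for TNS1, 1.89 for TP53INP2, 2.27 for CPNE2 and -1.64 for IGFBP3. In data outside the gene counts, alignments outside genes made up 22.12% in TRB T3 replicate 3 and 15.11% and 14.7% in the other TRB T3 libraries, against 11.09% to 13.64% in TRB vehicle, 12.22% to 13.73% in EV vehicle and 12.95% to 15.22% in EV T3 libraries.

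Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. Every other split also mixes libraries of both groups, so a real difference widens the spread within its sets. The counts of the other splits therefore show no level for chance, for genes or for lists. T3 in TRB cells called 6456 genes in the real split and at most 0 in any other, T3 in EV cells 660 and at most 5, TRB without T3 2220 and at most 0, and TRB with T3 5916 and at most 0; in each case 1 split, the real one, called as many. For lists the real counts were 17, 8, 14 and 16 and the highest others 12, 9, 10 and 12, so that for T3 in EV cells 2 splits called as many lists. For the interaction 100 of 200 splits of the treatment labels within pools were taken. Of these, 12 called as many genes as the real one (3470, highest other 5483) and 11 as many lists (15, highest other 19), so this count does not exclude chance. It points to a structure of the samples: the 11 other splits with as many genes were the 11 that kept the real grouping of the TRB libraries and so the T3 effect in them. The 88 that broke it mixed TRB libraries with and without T3 and called at most 0 genes.

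MT-RNR1 lay between 822 and 8050 CPM in EV vehicle libraries and between 58.3 and 95.8 CPM in EV T3 libraries, and between 1800 and 4770 and between 103 and 151 CPM in the TRB pool. Lower transcription of the whole mitochondrial genome would lower the 13 mitochondrial mRNAs too. Their median log2 fold change was 0.04 in EV and 0.36 in TRB cells, which argues against it. The mRNAs cannot speak to a change in the ribosomal RNAs alone, which was not tested. MT-RNR1 differed 9.78-fold between replicates of EV vehicle, where mitochondrial mRNAs differed by a median of 1.34-fold. A candidate explanation is uneven removal of ribosomal RNA, with vehicle and T3 libraries handled apart, while a change in the ribosomal RNAs alone stays open. The labels give no library batch, so T3 and such handling coincide in both pools.

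Because of that, the 660 calls for T3 in EV cells were weighed against depth, GC content and handling. Thinned to equal depth, 53.1% of the calls still tested were left with their direction (347 of 653), and with the GC trend removed 79.7% (513 of 644), which argues against either as the whole cause. Shared handling was to be excluded if over 20% of the calls differed between pools, and 59.4% did, but that criterion was wrong by design, since a receptor effect added in TRB cells makes calls from handling differ as well; handling and T3 cannot be told apart by it. Among the 382 protein-coding calls that differed, the extra change in TRB cells went in the EV direction in 85.1%. Handling of equal size in both pools and unrelated to the receptor would give about as many either way. Handling that was stronger in the TRB libraries would also lean in the EV direction, so this share does not exclude handling. For the 13 structured RNA calls 7.7% differed between pools, with a median ratio of 0.81, and handling stays open for them too. The calls for T3 in TRB cells carry the same limit, and handling was not weighed for them. Of these 6456 calls 71% were left with counts thinned to equal depth and 90.4% with the GC trend removed.

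Type I interferon genes were lower in the TRB pool without T3 (median log2 fold change -0.55, adjusted p = 0.0294 with an estimated correlation). With T3 the median was -0.42, and the call made with the preset correlation was lost (adjusted p = 0.402 with an estimated correlation). With an estimated correlation the call without T3 held in 2 of the 6 fits that left out 1 vehicle library and was lost in the others, without TRB vehicle replicates 1, 2 or 3 or EV vehicle replicate 1 (adjusted p = 0.0545, 0.0531, 0.0583 and 0.0543 with an estimated correlation). The size of the difference hardly moved: the median without 1 library lay between -0.525 and -0.595, and it was negative in all 9 pairs of 1 TRB and 1 EV vehicle library (-0.7 to -0.46). A single library as the cause is argued against by these medians. Estimated correlations were 0.34 to 0.367 in the fits that lost the call, 0.34 and 0.349 in those that kept it, and 0.322 with all libraries. Each fit without 1 library also had fewer residual degrees of freedom, which by itself raises these p-values. Beyond that, why calls were lost was not tested. Whether the receptor or some fixed difference between 2 stable pools lies behind it cannot be told apart, since each vector is 1 pool; the difference between the T3 effects on the list did not pass (camera adjusted p = 0.138), which shows no equality.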

How the results depend on the processing

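The thinned, protein-coding and GC-corrected fits, and the estimated correlation with 1 library left out, were chosen after seeing the data. Counts that moved by more than 1.5 times did so as follows; the cause was not tested. By DESeq2, T3 in EV cells called 372 genes in place of 660, TRB without T3 1417 in place of 2220, and the overlaps held 317 in place of 535 genes for T3 and 645 in place of 1037 for TRB. Thinning, which removes counts, gave 408 genes for T3 in EV cells and overlaps of 319 and 638. With an estimated correlation the lists called were 6 of 17 (T3 in TRB cells), 3 of 8 (T3 in EV cells), 5 of 14 (TRB without T3), 2 of 16 (TRB with T3) and 5 of 15 (interaction); 15 of these 21 held whichever library was left out. Leaving out 1 library gave 5592 to 6046 genes and 16 to 19 lists for T3 in TRB cells, 275 (without EV vehicle replicate 3; 396 without EV vehicle replicate 1 and 341 without EV T3 replicate 2) to 669 genes and 8 to 11 lists for T3 in EV cells, 1562 to 1846 and 13 to 18 for TRB without T3, 5109 to 5717 and 16 to 17 for TRB with T3, and 2910 to 3553 and 15 to 17 for the interaction; the overlaps ranged from 245 (also without EV vehicle replicate 3; 346 without EV vehicle replicate 1 and 307 without EV T3 replicate 2) to 534 for T3 and from 774 to 996 for TRB. Replicate numbers did not pair the samples: correlations of same-numbered libraries ran from -0.124 to 0.083. With the replicate block the counts were 6437, 647, 2195, 5898 and 3493 genes and 18, 8, 15, 16 and 16 lists, and the overlaps 522 and 1030. No named gene changed sign in any fit. Of 241 named gene results DESeq2 ended 4 calls, thinning 8 of 236, and the estimated correlation 49 of 70 list calls. The estimated setting also tests on the 8 residual degrees of freedom, so correlation between genes need not be why a list call ended. Immediate early genes (T3 in EV cells) lost the call at an estimate of 0.01, the preset value. The direction of each of the 70 list calls held in every camera fit. Among lists not called, fry pointed up where camera pointed down for apoptosis effectors (TRB without T3), NRF2 targets (TRB with T3) and mesenchymal and invasion genes (interaction). Medians near 0 changed sign for RUNX2 targets (TRB without T3, 0.005 and down to -0.181 when thinned), apoptosis effectors (interaction, 0.018 and down to -0.036) and immediate early genes (T3 in EV cells, 0.059 and -0.011 with the GC trend removed). Depth limits low genes most: 3 counts are 0.707 CPM in the shallowest library and 0.251 in the deepest.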

Other observations

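A systematic look at gene families, chosen after the data were seen, found nothing past the threshold. Protein-coding genes were grouped by the letters that begin their symbols, and the 206 families with 8 or more tested members were compared with all other genes by camera with an estimated correlation. After Benjamini-Hochberg adjustment 0 families passed in any of the 4 pairwise comparisons. At an unadjusted p under 0.05 there were 9 for T3 in TRB cells, 7 for T3 in EV cells, 9 for TRB without T3 and 6 for TRB with T3, and the smallest adjusted p was 0.0811, for TRB with T3. The 57 nuclear genes of the respiratory chain, a list fixed beforehand, had 17 members higher and 3 lower with T3 in TRB cells and did not pass (camera adjusted p = 0.444, and 0.83 with an estimated correlation).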
